A study of Saccharomyces cerevisiae with 33 samples.

How the data were processed

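Transcript levels were measured in haploid Saccharomyces cerevisiae of the a mating type (W303-1a, BAR1 deleted) on 33 cDNA arrays with 2 channels, 1 array for each of 33 combinations of dose and time. Per the labels, RNA of treated cells and RNA of untreated cells were labelled with different dyes by amino-allyl coupling and hybridised together, and the same untreated sample served every array. Per the file headers, the deposited scanner values are spot and local background brightness (intensity) with no background subtracted, a signal-to-noise minimum of 3 is recorded per spot and channel, and each ORF is spotted 2 times. The authors' value table holds log2 ratios of Cy5 over Cy3, centred near a median of 0 on each array. How that table was made is not stated, and its unit was read by setting each column against the intensities of its array (r 0.828 to 0.985, slope 0.771 to 1.05, 3.29 to 22.5% missing).

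The labels contradict each other on which dye marked the untreated cells. By a rule fixed in advance, the channel with the smaller spread between arrays was taken as the reference. Among the 200 probes whose ratio varied most, Cy5 varied more in 175 (87.5%; 80.1% of 1000 probes), so Cy3 was taken as the reference and ratios are Cy5 over Cy3, treated over untreated. No dye-swapped array exists, so a dye effect cannot be removed from comparisons with untreated cells and cancels in those between doses or times where it is constant.

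The intensities were corrected for background with limma's normexp method (offset 50), normalised within each array by loess with control spots at weight 0, centred on the median gene, and averaged over the 2 spots of an ORF. Spots marked to be ignored (0 to 42 per array) were left out. An ORF was tested if it was over the signal-to-noise minimum in either channel on at least 80% of arrays, which kept 6025 of 6177 ORFs, and 4860 were detected on all arrays. The 152 other ORFs and 41 features with other names were not tested. ORFs were matched by locus tag to a table of RefSeq genes (5663 of 6177 matched), used for symbols and for which genes are adjacent. No genome build is given for the probes, so no positions are printed.

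The median spot intensity of an array was 1072 to 4895 in Cy3 and 929 to 3068 in Cy5, and between 67.5 and 96.4% of spots in Cy3 and 84.9 and 98.0% in Cy5 passed the signal-to-noise minimum. Ratios of the 2 spots of an ORF correlated at 0.447 to 0.931 (median 0.747, across genes, which are not independent replicates). The correlation between arrays ran down to -0.224 with a median of 0.313 over 528 pairs. No dose and time was repeated, and the number of arrays limits the precision.

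The course was taken as the unit, with low-dose courses of 0.06, 0.2 and 0.6 nM and high-dose courses of 6, 60 and 600 nM. Limma (lmFit, then eBayes with an intensity trend, Benjamini-Hochberg adjusted p under 0.05) was fitted to the 6 course means over 30, 60 and 90 min (18 arrays), with the processing set given by the series design as a term. It tested the slope on log10 dose, the mean of each dose group against untreated cells, and the difference between the groups. A fit to the 24 arrays at 5, 30, 60 and 90 min with the course as a fixed block tested 30 against 5 min and 90 against 30 min in each dose group, and the difference between the groups in the early change. All limma tests are two-sided. On simulated data with 200 changed genes among 6025, the dose trend fit recovered 47.5, 83.75 and 100% of genes with slopes of 0.25, 0.5 and 1, with 9 false calls among 154, and the comparison of dose groups recovered 73.75, 96.25 and 100% of differences of 1, 2 and 4 log2 units, with 11 false calls among 187. The simulated noise was normal and independent between genes and courses, with no processing set or scan period effect and no array that stood apart. These rates therefore test the fits and need not hold for the measured data.

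The 19 gene lists were mating response, a-cell-specific genes, pheromone signalling components, negative regulators of pheromone signalling, cell and nuclear fusion, cell wall and integrity pathway, filamentation and invasive growth, G1/S genes, histones, G2/M genes, M/G1 genes, ribosomal proteins, ribosome biogenesis, environmental stress, glucose-repressed and respiration, phosphate starvation, amino acid biosynthesis, alpha-cell-specific genes, and meiosis and sporulation. Members that rose or fell were counted over all genes and adjusted over the list alone, for the dose trend and for the high-dose time contrasts. List shifts were tested with camera (preset correlation 0.01, and an estimated correlation), with fry and by an exact permutation of the list's course means over the 720 orders of the courses. Camera sets a list against the other genes, whereas fry asks only whether its members shifted in a common direction. Fry's separate test for change in either direction is given only where named. The dose midpoint of a list was read by linear interpolation on log10 dose with 2000 bootstrap draws over genes. List symbols not tested were GAS1, FLO11, FLO8, RPL29, FBP1, CAT8, POX1, PHM7, ARG5,6, MF(ALPHA)1 and SPR3.

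Genes were named by a rule: among genes past the threshold, the 10 largest positive and 10 largest negative estimates for the dose trend and the comparison of dose groups, and 5 and 5 for the other comparisons. Where none passed, the 3 positive and 3 negative estimates with the smallest p are named and said not to pass. For each list, up to 4 passing members and up to 2 others are named. Members of lists of at most 12 genes are allowed, and so is a fixed set: FUS1, FIG1, AGA1, FUS3, FAR1, SST2, MSG5, STE2, STE12, KAR4, PRM1, PRM2, PRM3, FIG2, MFA1, MFA2, BAR1, CLN1, CLN2, CLB2, CLB5, CLB6, SIC1, SWI5, CTS1, EGT2, HTA1 and HTB1. Other names are said to be chosen after their values were seen.

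The alternatives were no background subtraction, median centring in place of loess, print-tip loess over the 48 blocks, the authors' value table, no filter on dim spots, detection on all arrays, leaving out each course in turn, no processing set term, each processing set alone, course means that include 5 min, the 60 min arrays alone, all 33 arrays with the course as a random block, no course block, scan day as a block, eBayes without the trend, and for dose midpoints a Hill fit and all detected members. The tests, dose groups, lists, naming rule and these alternatives were fixed before the data were examined. Chosen after seeing the data were scan period as a term, with or without processing set, each scan period alone, and leaving out 3 arrays that stood apart on component 2 of the arrays (20.1% of variance). The counts of genes that moved the same way in each course, the list changes from 5 to 90 min and their slopes within batches were also chosen after seeing the data. The counts of genes cover only genes already called from the same courses, so they describe the calls and give no separate support. The 15, 120 and 150 min arrays entered no comparison except the alternative with all arrays, since not every course has them. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.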

Results

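The series followed how haploid budding yeast, Saccharomyces cerevisiae, changed its transcripts after exposure to mating pheromone at different strengths. Cells of the a mating type (strain W303-1a with BAR1 deleted) grew in rich glucose medium and received alpha factor, the peptide pheromone that alpha cells release, at 1 of 6 doses between 0.06 and 600 nM. BAR1 encodes the secreted protease that degrades alpha factor, so its deletion removes that route of pheromone loss. Each dose was 1 time course, sampled at 5, 15, 30, 60 and 90 min. Samples at 120 min were added for 0.06, 0.2 and 600 nM and a sample at 150 min for 0.06 nM, and the 600 nM course had no 15 min array. The 33 cDNA arrays had 2 colours, and every array set RNA from treated cells against RNA of the same untreated culture, taken before the pheromone was added. Log2 ratios below are treated over untreated. Of the 6177 ORFs on the array, 6025 were detected on at least 80% of the arrays and tested. The median spot was between 13.6 and 45.6 times its local background in the reference channel and between 21.5 and 125 times in the treated channel, and the number of arrays limits the precision. Each dose and time had 1 array, so values of single arrays carry no replicate error. Comparisons between doses used the mean of the 30, 60 and 90 min arrays of each course. The 3 low-dose courses (0.06, 0.2 and 0.6 nM) and the 3 high-dose courses (6, 60 and 600 nM) stand in for repeats, although the doses within each group differ, and whether the courses were independent cultures grown on different days is not stated.

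BAR1 itself was deleted in the treated and the untreated cells alike. Its log2 ratio ran from -0.22 to 0.47 over the 33 arrays, with a median of 0.05. The BAR1 spots passed the scanner's signal-to-noise minimum on 9 arrays in the reference channel and on 29 in the treated channel. Which part of BAR1 the deletion removed is not given in the sources used here, so this level does not check the genotype.

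The first question was which transcripts rose or fell with the dose of alpha factor. FIG1, a membrane protein needed for calcium entry during mating, rose by 1.98 log2 units per 10-fold increase in dose (SE 0.25, adjusted p = 0.00446, 6 courses), or 3.93-fold. PRM6, a pheromone-regulated membrane protein, rose 3.85-fold per 10-fold dose, PRM1, which acts in plasma membrane fusion, 2.49-fold, PRM3, which acts in fusion of the nuclear envelopes, 2.46-fold, and FIG2, a cell wall adhesin, 2.43-fold. PRM2 (2.40-fold), the a-specific gene ASG7 (2.35-fold) and the less characterised ORFs YOR343C (2.44-fold), YDR124W (2.29-fold) and YML048W-A (2.26-fold) completed the 10 steepest increases, 7 of which are in the mating response list. YML048W-A is absent from the RefSeq genes used, so its overlap with other genes was not checked. Its systematic name places it near PRM6 (YML047C), and whether its spot reads PRM6 transcripts was not tested. FIG1, PRM6, YOR343C and YML048W-A were dim in untreated cells, over the signal-to-noise minimum in the reference channel on 17, 10, 25 and 12 of the 33 arrays, so the sizes of their increases are less certain than those of bright genes.

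Of the 10 steepest decreases with dose, 3 were in the list of G1/S genes and 3 were histones. TOS4 fell by 0.72 log2 units per 10-fold dose (SE 0.08, adjusted p = 0.00211), and TOS6 fell by 0.72 (SE 0.08). The G1 cyclin CLN1 fell by 0.69 (SE 0.08), the histone H2A gene HTA2 fell by 0.68 (SE 0.12), the histone H4 gene HHF1 fell by 0.65 (SE 0.07) and the histone H2B gene HTB1 fell by 0.56 (SE 0.09). NRM1, a corepressor of G1/S transcription, fell by 0.61, the bud neck protein CSI2 fell by 0.55, and SNL1 and the homeobox repressor YHP1 each fell by 0.54. The histone genes come in near-identical copies, which cDNA spots cannot tell apart with certainty. Over all genes, limma called 165 genes higher and 80 lower with dose (Benjamini-Hochberg adjusted p under 0.05), and 1235 of the 6025 had an unadjusted p under 0.05. In 161 of these 245 genes, each high-dose course lay beyond each low-dose course.

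Among the 39 genes of a list of mating response genes, 30 rose with dose, none of them fell, and 33 passed when adjusted over the list alone. FUS1, needed for cell fusion, rose by 0.87 log2 units per 10-fold dose (SE 0.15, adjusted p = 0.016), the agglutinin anchor AGA1 by 0.82 (SE 0.14) and the transcription factor KAR4 by 0.89 (SE 0.09). Of the 18 pheromone signalling components, 6 rose (7 adjusted over the list alone), among them the MAP kinase FUS3 (0.58), the cyclin-dependent kinase inhibitor FAR1 (0.40) and the transcription factor STE12 (0.35), while the receptor gene STE2 did not pass (0.25, adjusted p = 0.195). Of the 12 negative regulators of the pathway, 6 rose (6 adjusted over the list alone). These included AFR1 (0.73), DIG2 (0.50), the phosphatase gene MSG5 (0.49) and the RGS protein gene SST2 (0.48). Of the 16 genes of cell and nuclear fusion, 12 rose (12 higher and 1 lower adjusted over the list alone), led by FIG1, PRM1, PRM3 and FIG2. Of the 7 a-cell-specific genes, ASG7 rose (2 adjusted over the list alone). The 7 include the deleted BAR1, which did not pass (0.07, adjusted p = 0.555) and counts in every value for this list, and the a-factor genes MFA1 (0.01, adjusted p = 0.945) and MFA2 (0.09, adjusted p = 0.493) did not pass. The lists overlap: FUS1, FIG1, FUS3 and others count in more than 1 of them. The mating response mean stood at 0.47 log2 units (1.38-fold) at 0.06 nM and at 2.92 (7.59-fold) at 600 nM.

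Of the 10 histone genes, 7 fell with dose and 9 did so adjusted over the list alone, with a list mean of -0.07 at 0.06 nM and -1.72 at 600 nM (0.304-fold). Of the 41 G1/S genes, 10 fell and 1 rose (17 lower and 1 higher adjusted over the list alone). CLN1, TOS4 and CSI2 were among those that fell. PCL2, a G1 cyclin that also stands in the mating response list, rose by 1.00. The S-phase cyclin CLB6 fell by 0.38, whereas CLB5 (-0.28, adjusted p = 0.0617) and the G1 cyclin CLN2 (-0.03, adjusted p = 0.88) did not pass. Of the 25 M/G1 genes, 4 genes rose and 1 fell (5 and 1 adjusted over the list alone). DSE1 (0.47), SCW11 (0.66) and the chitinase gene CTS1 (0.40), all linked to separation of daughter cells, and AMN1 (0.47) rose, and the replication factor CDC6 (-0.23), named here after its value was seen, fell. EGT2 (-0.05), SIC1 (-0.11) and SWI5 (0.02) did not pass. Of the 26 G2/M genes, BUD4, HST3 and AIM20 fell (3 adjusted over the list alone), and the mitotic cyclin CLB2 did not pass (-0.15, adjusted p = 0.155). Of the 23 measured genes of the cell wall and its integrity pathway, 6 rose (10 adjusted over the list alone), led by the aspartyl protease YPS1 (0.78), the chitin synthase CHS1 (0.70), the MAP kinase SLT2 (0.54) and PRM5 (0.46).

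Of 9 filamentation genes, 3 rose (TEC1, PGU1 and KSS1) and 2 fell (SVS1 and CLN1), or 5 and 2 adjusted over the list alone. Of 30 environmental stress genes, TPS2 (0.44) and GPD1 (0.47) rose (3 adjusted over the list alone), and of 26 amino acid biosynthesis genes ARG4 rose (0.21; 5 adjusted over the list alone). None of 30 ribosome biogenesis genes passed over all genes, and 10 fell adjusted over the list alone. None of 29 ribosomal protein genes, 22 genes of glucose repression and respiration, 14 of phosphate starvation and 11 of meiosis passed in limma, either way of adjusting. Of 3 alpha-cell genes 0 passed over all genes and 1, SAG1, rose adjusted over the list alone. The camera test with a preset correlation of 0.01 called 12 lists, but with an estimated correlation it called none. Its adjusted p with an estimated correlation was 0.116 for the mating response, fusion and ribosome biogenesis lists, 0.145 for pheromone signalling and histones, 0.156 for a-cell genes, 0.179 for negative regulators, the cell wall list and amino acid biosynthesis, 0.296 for G1/S, 0.36 for G2/M and 0.4 for environmental stress. Fry, which sets no list against the other genes, called mating response, a-cell genes and pheromone signalling (adjusted p = 0.00777 each). It also called fusion and ribosome biogenesis (0.00844 each), negative regulators and histones (0.0213 each) and the cell wall list (0.025). By fry G1/S (0.0811), G2/M (0.138), environmental stress (0.199) and amino acid biosynthesis (0.0533) did not pass for a common direction. Fry's test for change in either direction did call these lists (adjusted p = 0.00694, 0.00854, 0.00854 and 0.0386). That test also called filamentation (0.00192), M/G1 (0.00854) and meiosis (0.000426), but not ribosomal proteins, respiration, phosphate starvation or alpha-cell genes.

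The mean of each list was then set against log10 dose over the 6 courses with a two-sided exact permutation test of all 720 orders, 19 lists in all. For the mating response, Pearson's r was 0.977 (exact p = 0.00139, the smallest these orders can give, adjusted p = 0.0226) and Spearman's rho was 1 (exact p = 0.00278, adjusted p = 0.0264), and r without the 2 doses farthest from the median dose was 0.985. For the histones, r was -0.952 (exact p = 0.00833, adjusted p = 0.0226) and rho was -1 (exact p = 0.00278, adjusted p = 0.0264), with r = -0.965 without the 2 farthest doses. The 5 other lists past the threshold had r = 0.967 (a-cell genes, exact p = 0.00417), 0.952 (pheromone signalling, exact p = 0.00694), 0.952 (negative regulators, exact p = 0.00694), 0.966 (fusion genes, exact p = 0.00556) and -0.946 (ribosome biogenesis, exact p = 0.00833), each with an adjusted p of 0.0226. Their rho was 0.943 in the 4 lists that rose and -0.943 in ribosome biogenesis (exact p = 0.0167, adjusted p = 0.0396), and r without the 2 farthest doses was 0.911, 0.954, 1.00, 0.980 and -0.909 in the same order. The G1/S list passed by rho (-0.943, exact p = 0.0167, adjusted p = 0.0396) and not by r (-0.88, exact p = 0.0236, adjusted p = 0.0561, -0.868 without the 2 farthest doses). The arrays had been processed in 2 sets, with 0.06, 0.6 and 60 nM in set 1 and 0.2, 6 and 600 nM in set 2, and scanned in 2 periods, with 0.6, 6 and 60 nM in period 1. Within set 1, set 2, period 1 and period 2, the mating response slope per 10-fold dose was 0.73, 0.67, 0.72 and 0.64, the histone slope was -0.52, -0.44, -0.46 and -0.43 and the ribosome biogenesis slope was -0.11, -0.11, -0.08 and -0.10, with 3 courses in each. The same 4 slopes were 0.33, 0.28, 0.35 and 0.32 for the a-cell genes, 0.18, 0.17, 0.17 and 0.15 for pheromone signalling, 0.24, 0.25, 0.33 and 0.20 for the negative regulators and 0.89, 0.81, 0.87 and 0.75 for the fusion genes. With 5 courses the smallest possible exact permutation p is 0.00833 (120 orders), which is 0.158 after adjustment if 1 list alone reaches it. Leaving out 0.06, 0.6, 6, 60 or 600 nM in turn left 0 lists past the threshold and leaving out 0.2 nM left 7, so the lost calls say little about stability. Over these 6 fits the mating response slope was 0.64 to 0.80 and the histone slope -0.58 to -0.42, with an adjusted p of 0.0452 to 0.0792 for each.

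**Figure D1:**
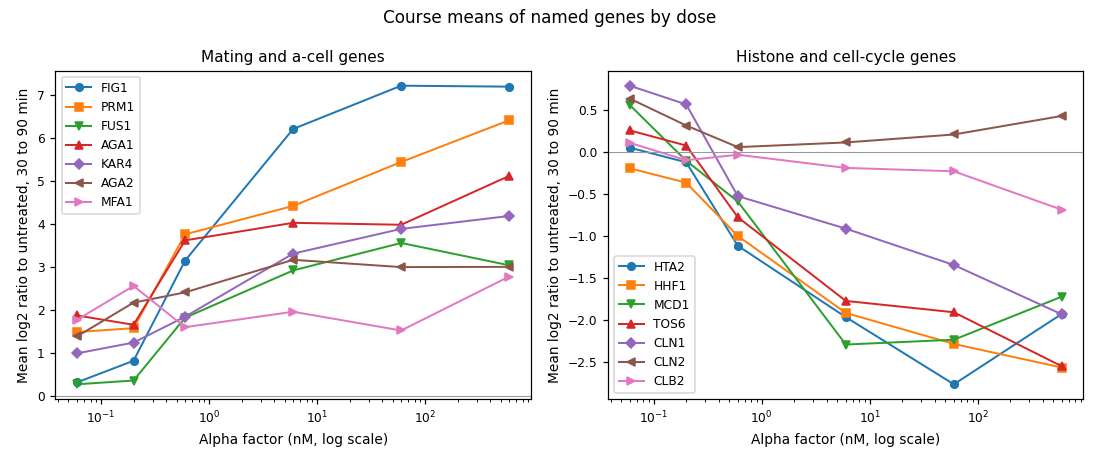
Mean log2 ratio to untreated cells over 30, 60 and 90 min (vertical axis) against the dose of alpha factor in nM on a log scale (horizontal axis), 1 point per course, for mating and a-cell genes (left) and histone and cell-cycle genes (right). FIG1 had a slope of 1.98 log2 units per 10-fold dose, HHF1 a slope of -0.65 and MFA1, which did not pass, a slope of 0.01.

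The dose at which a list's passing members reached the midpoint between their means at 0.06 and 600 nM was read by interpolation, with no test. It was 1.79 nM for the mating response (95% interval 1.08 to 3.10 from resampling genes, which are not replicates), 1.62 nM for fusion genes (0.759 to 3.41), 1.27 nM for pheromone signalling (0.508 to 7.08), 3.54 nM for the negative regulators (upper bound 11.6), 1.64 nM for the cell wall list (0.539 to 6.56), 1.42 nM for G1/S genes (0.824 to 2.36) and 1.12 nM for histones (0.590 to 2.89). For the 4 M/G1 genes that rose, it was 18.8 nM (11.3 to 24.3). Their means did not rise steadily (0.29, -0.52, -0.08, 0.19, 1.47 and 1.35 from the lowest to the highest dose), so that midpoint is poorly defined. No midpoint was adjusted for processing set, and the intervals do not cover the spread between courses. No dose lay between 0.6 and 6 nM, so these midpoints mostly fall in an interval without data. A fitted Hill curve moved the M/G1 value to 6.99 nM and the G1/S value to 0.601 nM. Taking all measured members moved the values to 30.1 nM for M/G1, 0.400 nM for G1/S, 6.37 nM for pheromone signalling, 7.96 nM for the negative regulators and 0.563 nM for the cell wall list, and the 60 min arrays alone moved the histone value to 0.596 nM.

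The call count for the dose trend was 0 without the 0.2 nM course and 64 without the 60 nM course, against 245 with all 6. Within set 1, set 2, period 1 and period 2 alone it was 0, 60, 22 and 148, it was 374 after print-tip loess, 151 without the processing set term, 129 with the 5 min arrays included, 70 on the 60 min arrays alone and 595 with set and period both as terms. Each of the 31 called genes followed through up to 24 alternatives lost its call in at least 2 of them: STE12 in 10, CTS1 in 9, YML048W-A and FIG2 in 8 and NRM1, SST2 and CLB6 in 7. Within scan period 1 the slope was -0.07 for NRM1, 0.18 for AGA1, -0.41 for CLN1, -0.22 for CLB6, 0.84 for PRM1 and 0.80 for PRM2, and it was 2.10 for YML048W-A and 0.78 for MSG5. NRM1 had -0.33 on the authors' value table, CSI2 had -0.33 on all 33 arrays, and YML048W-A had 0.74 without the 60 nM course and 1.84 without 600 nM.

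A second comparison asked which transcripts in the high-dose courses differed from those of untreated cells. FIG1 stood 127-fold above the untreated level (6.99 log2 units, SE 0.43, adjusted p = 1.65e-05, 3 courses), PRM6 77.0-fold, PRM1 45.5-fold, ASG7 36.1-fold and FIG2 26.7-fold. FIG1 and PRM6 were over the signal-to-noise minimum in the reference channel on 17 and 10 of 33 arrays, and without background subtraction they stood 6.26 and 5.47 log2 units higher, so their fold sizes depend on the handling of background. AGA1 was 21.3-fold higher, KAR4 14.1-fold, FUS1 9.66-fold, FUS3 5.07-fold, SST2 4.09-fold, MFA1 3.83-fold, FAR1 3.43-fold, STE12 2.89-fold and the receptor gene STE2 2.10-fold (adjusted p = 0.0155). HTA2 fell to 0.200 of its untreated level (-2.32, SE 0.19, adjusted p = 7.24e-05), HHF1 to 0.206, HTB2 to 0.213, the cohesin subunit MCD1 to 0.234 and TOS6 to 0.236, and CLN1 fell to 0.372. CLN2 (0.25, adjusted p = 0.263), CLB2 (-0.34, adjusted p = 0.105) and SWI5 (-0.09, adjusted p = 0.632) did not pass. In limma 429 genes were higher and 349 lower, 1836 had an unadjusted p under 0.05, and 92 of the calls were at least 2-fold higher and 38 at least 2-fold lower. The sign was the same in all 3 courses for 746 of these 778 genes.

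This test leaves out the spread of the untreated cells, whose RNA was a common reference, and no dyes were swapped, so a dye effect can be part of it. The reference was taken before alpha factor was added, and no untreated culture was followed over time. A change with time in culture or handling therefore cannot be told apart from an effect of alpha factor in this comparison. The count was 74 without the 60 nM course, 337 without 600 nM and 382 without 0.2 nM, 129 and 116 within processing sets 1 and 2, 201 and 264 (131 higher and 133 lower) within scan periods 1 and 2, 375 on the 60 min arrays alone and 1366 with set and period both as terms. Of 28 called genes followed through up to 24 alternatives, 21 kept their call in all. CLB5 (-0.57) lost it in 12, CTS1 (0.81) in 8, CLN1 in 3, STE2 in 2 and TOS6, MSG5 and PRM3 in 1 each. STE2 stood at 0.67 without the 600 nM course and within scan period 1, which give the same estimate. Within scan period 2, where 600 nM is the only high-dose course, it stood at 1.93.

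In the low-dose courses 5 genes stood above the untreated level. MFA1, a gene of the a-factor precursor, was 4.33-fold higher (2.12 log2 units, SE 0.14, adjusted p = 0.000458, 3 courses), AGA2, the adhesion subunit of a-agglutinin, 4.04-fold (adjusted p = 0.0017) and MFA2, the other a-factor gene, 2.18-fold (adjusted p = 0.0205). YIL080W, an ORF of the Ty3 retrotransposon, was 3.59-fold higher and the carbonic anhydrase gene NCE103 1.70-fold (adjusted p = 0.0307 each). All 5 had the same sign in the 3 courses. Over 24 alternatives the call was lost in 14 for NCE103 (estimates of 0.48 to 1.05 log2 units), in 7 for MFA2 (0.51 to 1.58), in 4 each for YIL080W and MFA1 and in 3 for AGA2. KAR4 (1.33, adjusted p = 0.0633), AGA1 (2.34, adjusted p = 0.0655), PRM1 (2.18, adjusted p = 0.111), FUS1 (0.71, adjusted p = 0.235) and FIG1 (2.47-fold, adjusted p = 0.234) did not pass. In limma 5 genes were higher and 0 lower, and 814 had an unadjusted p under 0.05.

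The limits of the comparison with untreated cells hold here too, including that of time in culture. For the dose trend in limma, MFA1 (0.01, adjusted p = 0.945), MFA2 (0.09, adjusted p = 0.493) and AGA2 (0.34, adjusted p = 0.0831) did not pass, whereas YIL080W did. The count against untreated cells was 0 without the 0.2 nM course, 2 without 60 nM, 21 without 0.6 nM (5 higher and 16 lower), 24 without 600 nM (16 and 8) and 47 without 6 nM (16 and 31). It was 0 within each processing set, 13 (12 and 1) and 39 (8 and 31) within scan periods 1 and 2, 8 (6 and 2) with scan period and 11 (8 and 3) with both as terms, and 19 on the authors' value table (11 higher and 8 lower), where 5395 genes were tested. It was 5 higher and 1 lower after print-tip loess or without background subtraction, 9 (6 and 3) on the 60 min arrays alone, 17 (15 and 2) with the 5 min arrays included, 382 (154 higher and 228 lower) on all 33 arrays with the course as a random block and 10 (all higher) without 3 arrays that stood apart (0.2 nM at 60 min, 6 nM at 15 and 90 min).

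The high-dose and low-dose courses were also compared directly, a contrast in which the reference and any constant dye effect cancel. FIG1 was 51.3-fold higher in the high-dose courses (5.68, SE 0.62, adjusted p = 0.00347), PRM6 46.3-fold, FIG2 15.6-fold, YML048W-A 13.8-fold, ASG7 13.4-fold, YOR343C 13.3-fold, PRM3 10.9-fold and PRM2 9.33-fold, with YDR124W at 3.45 and PRM1 at 3.33 log2 units. The dim genes FIG1, PRM6, YML048W-A and YOR343C stood at 5.02, 4.62, 3.12 and 3.18 log2 units without background subtraction. MCD1 was lower, at 0.240 of its low-dose level (-2.06, SE 0.30, adjusted p = 0.00986), as were HTA2 (0.245), HTB2 (0.254), TOS4 (0.260), TOS6 (0.260), HHF1 (0.291), HTB1 (0.321), HHF2 (0.329), HTA1 (0.345) and RNR1, the large subunit of ribonucleotide reductase (0.349). AGA1 (2.08, adjusted p = 0.0952), CLN1 (-1.73, adjusted p = 0.0593), MFA1 (-0.18, adjusted p = 0.734) and MFA2 (0.26, adjusted p = 0.555) did not pass. In limma 72 genes were higher and 28 lower, 910 had an unadjusted p under 0.05, and in 89 of the 100 each high-dose course lay beyond each low-dose course. The count was 0 without the 60 nM course, 1 without 0.2 nM, 58 without 0.06 nM and 178 without 6 nM. It was 1 and 0 within processing sets 1 and 2, 3 and 99 within scan periods 1 and 2, and 50 with scan period as the term. For this contrast the fit within set 1 gives the same result as leaving out 0.2 nM, and within set 2 the same as leaving out 60 nM. The counts of lost calls below therefore hold each of these fits more than once. Each of the 27 called genes followed lost its call in at least 4 of up to 24 alternatives. The call was lost in 11 for PRM2 and FAR1, in 9 for PRM1, FUS3 and STE12, in 8 for SST2, in 7 for TOS6 and MSG5 and in 6 for TOS4, HTA2, HHF1 and HHF2. Within scan periods 1 and 2 the difference was 1.07 and 4.62 log2 units for PRM2, 1.17 and 4.88 for PRM1, 3.56 and 6.62 for FIG1, 2.20 and 3.92 for FIG2, -1.04 and -2.38 for TOS4 and -1.25 and -1.89 for HTA2. In period 1 TOS6, HTB2, HHF1, HTB1, HHF2 and HTA1 also lay nearer 0 than over all courses by more than 1.5 times. The fit within period 1 sets 6 and 60 nM against 0.6 nM alone, and that within period 2 sets 600 nM against 0.06 and 0.2 nM. The doses compared lie closer together in period 1, so a smaller difference there can follow from dose. These values therefore cannot separate an effect of scan period from one of dose.

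The time contrasts asked which transcripts changed after 5 min, early and late within a course. A change before 5 min does not enter them, and the mating response mean already stood at 1.52, 1.65 and 1.55 log2 units at 5 min of 6, 60 and 600 nM. No untreated culture was followed, so a contrast within 1 dose group does not separate alpha factor from time in culture. Between 5 and 30 min of a high dose, FIG1 rose 16.5-fold (4.04, SE 0.46, adjusted p = 3.86e-05, 3 courses), PRM3 6.65-fold, CIK1, a partner of the kinesin KAR3, 5.26-fold, YDR124W 3.58-fold and PRM9 3.56-fold. TOS6 fell to 0.313 of its 5 min level (-1.68, SE 0.30, adjusted p = 0.00402), HHF1 to 0.338, HTA2 to 0.433, CDC21 to 0.439 and SYF1 to 0.439. FUS1 (-0.04, adjusted p = 0.99), FUS3 (0.05, adjusted p = 0.988), SST2 (0.02, adjusted p = 0.994) and AGA1 (0.44, adjusted p = 0.91) did not pass, and neither did FAR1 (-0.58, adjusted p = 0.395) or STE12 (-0.65, adjusted p = 0.104). Of the mating response list 10 rose (20 higher and 2 lower adjusted over the list alone), with FIG1, PRM3, CIK1 and ASG7 (1.78) the largest. Of the fusion genes 6 rose (8 adjusted over the list alone) and of the a-cell genes ASG7 and MFA1 (4 adjusted over the list alone). Of the histones 7 fell (9 adjusted over the list alone), and of the G1/S genes CDC21, TOS4 and RNR1 fell (10 lower and 1 higher adjusted over the list alone). These 4 lists other than G1/S were also called by camera with an estimated correlation: adjusted p = 0.0261 for mating response and for fusion, 0.0148 for a-cell genes and 0.0077 for histones, against adjusted p = 0.063 for G1/S. Called with the preset correlation but not with an estimated one were the negative regulators and the glucose repression list (adjusted p = 0.248 each), ribosome biogenesis (adjusted p = 0.344), environmental stress (adjusted p = 0.4) and M/G1 (adjusted p = 0.419). Fry called mating response and fusion (adjusted p = 0.00784 each), a-cell genes (0.00261), histones (0.000702) and G1/S (0.0425), and no other list, in a common direction. Its test for change in either direction also called pheromone signalling (adjusted p = 0.000155), the negative regulators (0.000145) and meiosis (0.00652). SAG1, the alpha-cell agglutinin gene, rose by 1.69 (SE 0.27, adjusted p = 0.00129), the signalling gene DIG2 by 1.06, the regulator AFR1 by 1.18 and the phosphate pathway gene PHO81 by 0.72, whereas SVS1 fell by 1.16. DIG2 and AFR1 were the 2 negative regulators that passed (2 adjusted over the list alone), and 1 signalling component rose and 1 fell adjusted over the list alone.

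In limma 28 genes rose and 17 fell over this interval, and 432 had an unadjusted p under 0.05. Of the 45, which were called from these same courses, 44 moved the same way in all 3. The count was 6 (all higher) without the 600 nM course, 15 without 60 nM (6 higher and 9 lower), 2 (both higher) without the course as a block, and 30 on the authors' value table (15 higher and 15 lower), where 3639 genes were tested against 6025. Over up to 16 alternatives FIG1 kept its call in all, and the 13 other genes followed lost theirs in 1 to 4, MFA1 in 4 and CDC21 and YDR124W in 3.

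**Figure D2:**
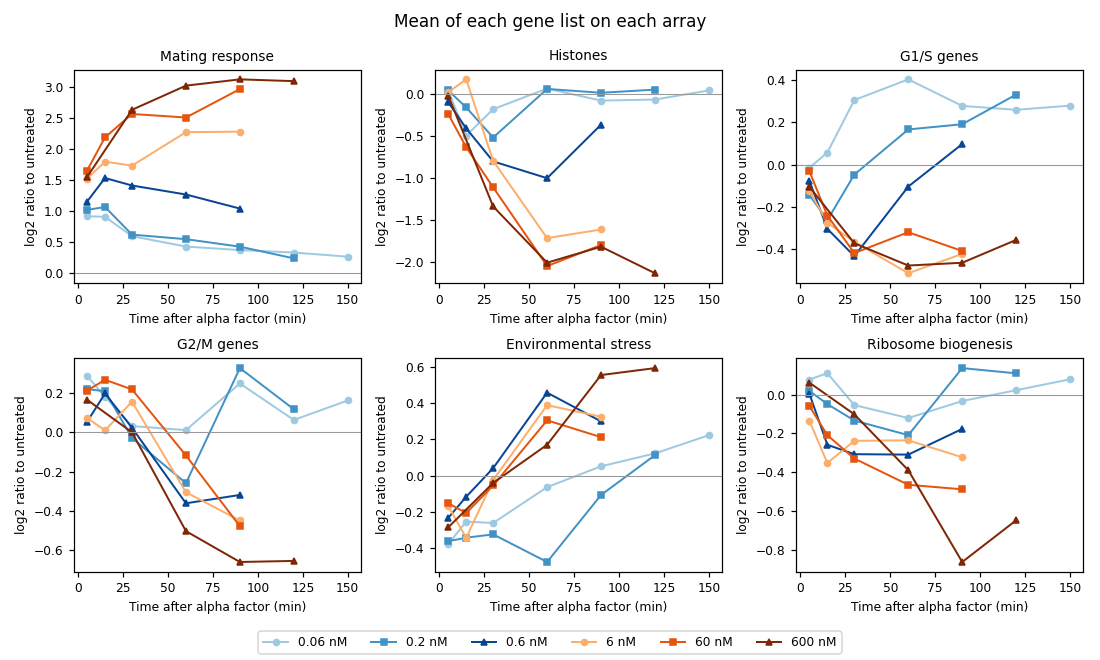
Mean log2 ratio to untreated cells of 6 gene lists (vertical axis) against minutes after alpha factor (horizontal axis), 1 line per dose and 1 point per array, with no replicates. The mating response list stood between 0.92 and 1.65 on the 5 min arrays and between 0.37 (0.06 nM) and 3.12 (600 nM) at 90 min.

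Between 30 and 90 min of a high dose, AIM20 fell to 0.225 of its 30 min level (-2.15, SE 0.30, adjusted p = 0.000217, 3 courses), the membrane protein MRH1 to 0.255, the mitotic cyclin CLB1 to 0.270, YHP1 to 0.275 and EGT2, which acts in cell separation, to 0.297. The largest increases were those of YCL074W, a pseudogene in the reference table, 3.75-fold (1.91, SE 0.27, adjusted p = 0.000286), the glutaredoxin gene GRX3 3.55-fold, YGL230C 3.28-fold, TMA10 3.04-fold and YHR138C 2.73-fold. YGL230C and YCL074W were over the signal-to-noise minimum in the reference channel on 10 and 23 arrays. Of the 26 G2/M genes 8 fell (13 adjusted over the list alone), including AIM20, CLB1, HOF1 (-1.65), the kinase CDC5 (-1.46) and CLB2 (-1.11, adjusted p = 0.0111), and the list was called with an estimated correlation (adjusted p = 0.0272). Of the 25 M/G1 genes 7 fell (11 adjusted over the list alone), with EGT2, PCL9 (-1.32), DSE3 (-1.27) and SIC1 (-0.88) among them. Of the histones 4 fell (7 adjusted over the list alone), led by HTA2 (-1.26) and HTB2 (-1.14). Of the environmental stress list 5 rose and 1 fell (14 and 1 adjusted over the list alone): HSP12, a small heat-shock protein, rose by 1.31 and MSC1 by 1.09, whereas YGP1 fell by 1.29. From 5 to 90 min the stress list mean rose in all 6 courses, by 0.43, 0.26, 0.53, 0.49, 0.36 and 0.84 from the lowest to the highest dose. A relation of this change to log10 dose did not pass (r = 0.649, exact permutation p = 0.16, adjusted p = 0.253) and stays unresolved with 6 courses. No untreated culture was followed over time, and the late change was not tested between dose groups. For this list, a change with time in culture thus cannot be told apart from an effect of alpha factor. The same limit holds for the other late calls taken alone. From 5 to 90 min, the change in the G2/M list followed dose (r = -0.935, exact permutation p = 0.00972, adjusted p = 0.0264). That in the M/G1 list did not pass (r = -0.194, exact permutation p = 0.703). Of the ribosome biogenesis list SSF1, NOP1 and NOP58 fell (5 adjusted over the list alone). The adjusted p with an estimated correlation was 0.164 for the M/G1, histone, stress, ribosome biogenesis, mating response and a-cell lists and 0.366 for the fusion list. Fry called G2/M (adjusted p = 0.00103), histones (0.0156), stress (0.03), and M/G1 and a-cell genes (0.031 each). It also called ribosome biogenesis (0.0391) and mating response (0.0406), but not fusion (0.175), for a common direction. Fry's test for change in either direction called fusion (adjusted p = 0.0147), among other lists.

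Of the mating response genes PRM8 (0.92), PRM10 (0.88) and HYM1 (0.89) rose in the late interval (10 adjusted over the list alone), while FIG1 (0.85, adjusted p = 0.378), PRM3 (1.12, adjusted p = 0.0521) and FUS1 (0.37, adjusted p = 0.36) did not pass. Of the cell wall list KRE6 rose (0.87), and PIR1 (-0.94) and CWP1 (-0.66) fell (3 and 2 adjusted over the list alone). DIG2 rose by 0.97, the G1/S gene MSH6 by 1.39 and the amino acid biosynthesis gene HIS3 by 0.59, whereas the phosphatase gene PHO5 fell by 1.07. In limma 103 genes rose and 57 fell, 964 had an unadjusted p under 0.05, and 159 of the 160 moved the same way in all 3 courses. The count was 34 without the 600 nM course (10 higher and 24 lower), 67 without 60 nM (39 and 28) and 256 without 0.2 nM (160 and 96). It was 28 (11 and 17) without the course block, 48 (22 and 26) with scan day as a block, 87 (50 and 37) on the authors' value table, where 3639 genes were tested against 6025, and 335 (218 and 117) without the 3 arrays that stood apart. Of 13 called genes followed through up to 16 alternatives, 8 kept their call in all, and SIC1, HTB1 and CLB2 lost it in 3. On the authors' value table the falls of AIM20 and YHP1 were smaller by over 1.5 times, with YHP1 at -1.07.

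In the low-dose courses KAR4 fell to 0.391 of its 5 min level by 30 min (-1.36, SE 0.23) and STE12 to 0.509 (-0.97, SE 0.17), while MFA1 rose 1.84-fold (0.88, SE 0.16), each with an adjusted p of 0.0303 and the same sign in 3 of 3 courses. Over 16 alternatives the call was lost in 11 for STE12 and for MFA1 and in 7 for KAR4. AGA1 (-1.35, adjusted p = 0.306), FUS1 (-0.68, adjusted p = 0.598) and PRM1 (-1.54, adjusted p = 0.603) did not pass. These were all 3 calls in limma, and 450 genes had an unadjusted p under 0.05. Between 30 and 90 min limma called 0 genes, with 476 at an unadjusted p under 0.05. The smallest p-values there belonged to HSP12 (1.13, adjusted p = 0.288), SMC2 (0.96) and TPO2 (1.01) among positive estimates and to AGA2 (-1.01, adjusted p = 0.293), MFA2 (-0.88) and SFC1 (-0.73) among negative ones. The early count was 0 without the 0.06 or the 60 nM course and 1 without 0.6 or 6 nM, 0 after print-tip loess or without the course block, and 1, a gene that fell, after median centring or on the authors' value table. The late count was 1 without the 60 nM course and 9 without the 3 arrays that stood apart.

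Whether the early change differed between the high-dose and low-dose courses was tested as an interaction. PRM3 rose by 2.45 log2 units more in the high-dose than in the low-dose courses (SE 0.43, adjusted p = 0.0351), and RVS161, an amphiphysin-like protein needed for cell fusion, by 1.22 (SE 0.21, adjusted p = 0.0351). For both, the change in each high-dose course lay beyond that in each low-dose course. FIG2 (1.99, adjusted p = 0.186), FIG1 (2.70, adjusted p = 0.319), AGA1 (1.79, adjusted p = 0.319) and KAR4 (0.93, adjusted p = 0.992) did not pass. In limma these were the 2 calls, and 268 genes had an unadjusted p under 0.05. The count was 0 without the 0.06, 0.2, 60 or 600 nM course, 7 without 6 nM and 10 without 0.6 nM (neither PRM3 nor RVS161 among the 10), 0 without the course block or the intensity trend, and 9 with scan day as a block. Over 16 alternatives PRM3 lost its call in 8 (estimates of 2.06 to 2.88) and RVS161 in 7 (1.06 to 1.29).

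On the 5 min arrays the mating response mean was 0.92 log2 units at 0.06 nM, 1.02 at 0.2 nM, 1.15 at 0.6 nM, 1.52 at 6 nM, 1.65 at 60 nM and 1.55 at 600 nM. Its correlation with log10 dose did not pass over 19 lists (r = 0.913, exact permutation p = 0.025, adjusted p = 0.422; rho = 0.943, exact permutation p = 0.0167, adjusted p = 0.317; r = 0.980 without the 2 farthest doses). From 5 to 90 min the mean moved by -0.55, -0.59, -0.11, 0.76, 1.31 and 1.57 in the same order of doses. Across the 6 courses this change had r = 0.980 (exact permutation p = 0.00278, adjusted p = 0.0176) and rho = 0.943 (exact permutation p = 0.0167, adjusted p = 0.0396) with log10 dose, and r = 0.993 without the 2 farthest doses. The slope of the change per 10-fold dose was 0.60 over all courses and 0.63, 0.61, 0.71 and 0.56 within set 1, set 2, period 1 and period 2.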

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

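The splits of the samples, the test of the genes beside SAG1 and the tests of adjacent genes were written before their results were seen. The tests of the early mating response at low dose, the test for alpha cells, and the correlations of the change from 5 to 90 min were chosen only after the result was seen.

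The mating response list stood at 0.92 (0.06 nM) and 1.02 (0.2 nM) log2 units above untreated cells at 5 min and at 0.37 and 0.43 at 90 min. A dye or spot effect shared by all arrays is constant and so does not account for the fall itself (the list fell by 0.55 and 0.59, past the middle 95% of 10000 random lists of like brightness, -0.10 to 0.09 and -0.13 to 0.14). This comparison is part of the pattern as it was seen, and the effect stays open for what remained at 90 min. A stress of handling at the first sampling would raise the environmental stress list at 5 min, but that list moved up from 5 to 90 min by 0.43 and 0.26, above the random lists (up to 0.11 and 0.17). The stress list also rose over this time in every other course (up to 0.84 at 600 nM). A rise with time could hide an early effect, so this comparison cannot decide on handling. At 5 min the list stood at -0.38 and -0.36 against untreated cells. A response whose length depends on dose stays open as a candidate explanation. The 5 to 90 min change followed dose over the 6 courses (exact permutation p = 0.00278), but this test includes the courses that set the pattern and does not separate the length of a response from its size. Each value comes from 1 array, and the low-dose courses have no untreated culture followed over time.

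SAG1, the agglutinin gene of alpha cells, rose by 1.69 log2 units (SE 0.27) from 5 to 30 min of a high dose in cultures of a cells. A share of alpha cells that grew from 5 to 30 min would raise other alpha-cell transcripts. STE3 (-0.05, SE 0.19) and MF(ALPHA)2 (-0.0244, SE 0.19) stayed below the SAG1 change by more than 2 SE, while MF(ALPHA)1 was not tested. A constant share of alpha cells would leave both unchanged over this time, so this comparison does not exclude alpha cells in the cultures. Transcripts of a neighbouring gene on the probe would move MRX12 or APL1, which changed by -0.24 (SE 0.19) and 0.21 (SE 0.15). Hybridisation of another transcript to the SAG1 probe was not tested, so a response of SAG1 itself is a candidate explanation and no more.

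Genes called for the dose trend lay next to each other, in the same direction, in 16 pairs, against a mean of 4.94 (middle 95% 1 to 10) in 10000 random placements of the 232 placed calls, which argues against chance adjacency. Divergent pairs made up 8 of these against 1.26 expected (0 to 4), among them HTB1 with HTA1, HHF1 with HHT1, PEX34 with KAR4 and PEX29 with DIG2, so a shared promoter region may account for part of the pattern. Tandem and convergent pairs made up the other 8, at the upper bound of the random range (3.68, 1 to 8), so transcripts that run into the next gene cannot be told apart from chance: the bound written in advance is met only at its edge, and the verdict was set after the value was seen. The pairs named here were chosen after their values were seen.

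For the dose trend, 1 of 100 orders of the doses over the courses, the real one, gave as many genes (245, highest other order 198, which was the reverse order of doses). This share of 1 in 100 is the smallest these orders can give. It argues against chance but does not exclude it. For the high-dose minus low-dose comparison, 1 of 9 splits that could be fitted gave as many genes (100, highest other 0), too few splits for a share under 0.05. The same holds for 30 against 5 min (45 genes) and 90 against 30 min (160 genes) in the high-dose courses, 30 against 5 min in the low-dose courses (3 genes) and the difference in early change (2 genes), each 1 of 10 splits with 0 as the highest other. For 90 against 30 min in the low-dose courses, all 10 splits gave 0 genes.

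The early change differed between dose groups, by the test of the difference itself, for PRM3 (2.45 log2 units) and RVS161 (1.22), calls that were lost in 8 and 7 of 16 alternatives. The change from 5 to 90 min differed between doses by an exact permutation test for 10 of the 19 lists. Its r with log10 dose was 0.980 for the mating response, 0.951 for a-cell genes, 0.985 for pheromone signalling, 0.902 for the negative regulators, 0.974 for fusion, 0.939 for the cell wall list, -0.920 for G1/S, -0.917 for histones, -0.935 for G2/M and -0.897 for ribosome biogenesis. Their exact permutation p ran from 0.00139 to 0.0236 (adjusted p 0.0176 to 0.0449). By rho the same lists had an adjusted p of 0.0396, except G1/S and histones at 0.0633, which did not pass. The size of the change per 10-fold dose varied between batches in some lists. For ribosome biogenesis the slope was -0.21 over all courses and -0.11, -0.30, -0.12 and -0.24 within set 1, set 2, period 1 and period 2. For the negative regulators it was 0.17 over all courses and 0.23, 0.12, 0.32 and 0.15 in the same order.

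Arrays outside the comparisons also showed the mating response above random lists, in log2 units over untreated cells: 0.91 at 0.06 nM and 15 min, 0.33 at 120 min and 0.27 at 150 min, 1.07 at 0.2 nM and 15 min and 0.24 at 120 min. At 15 min the mean was 1.53 at 0.6 nM, 1.80 at 6 nM and 2.19 at 60 nM, and at 600 nM it was 3.09 at 120 min.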

How the results depend on the processing

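The settings with scan period and the one without 3 arrays that stood apart were chosen only after the result was seen. Beyond the counts below, of the results for the named genes 5514 kept their side of the threshold, 104 came to pass and 458 no longer passed. For single lists the counts were 208, 4 and 35, and of the dose midpoints 17 stayed within their interval and 4 left it. Among these the sign changed in 154 results for named genes and 9 for lists, 0 of which passed in either fit. Of all 778 genes, named or not, that were called at high dose against untreated cells, 777 kept their sign after print-tip loess, 776 within processing set 2 and 771 within scan period 2; with the authors' table or another filter, sign changes were not separated from genes no longer tested. Signal over background (median spot 13.6-fold or more in Cy3) limits dim genes such as PRM6 and FIG1. The cause of the moves was not tested.

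Genes called moved by over 1.5 times as follows. Print-tip loess gave 374 for the dose trend, 0 for the early change at low dose and 1 for the difference in early change. Median centring gave 1 for the early change at low dose. The authors' value table, with 5395 genes tested over courses and 3639 over times against 6025, gave 19 for low dose against untreated cells, 87 for the late change at high dose and 1 for the early change at low dose. Without the processing set term the dose trend had 151. For the dose trend, high dose, low dose and high minus low, processing set 1 alone gave 0, 129, 0 and 1 and set 2 alone 60, 116, 0 and 0. With 5 min included in the course mean, the dose trend had 129 and low dose 17. The 60 min arrays alone gave 70, 375 and 9 for dose trend, high and low dose, and all 33 arrays gave 382 for low dose. Without the course block the early and late changes at high dose had 2 and 28, and the early change at low dose and the difference 0 each. Scan day as a block gave 48, 1 and 9 for the late change at high dose, the early change at low dose and the difference, and eBayes without the trend gave 0 for the difference. Scan period as a term gave 8 for low dose and 50 for high minus low, and both terms gave 595, 1366 and 11 for dose trend, high and low dose. Period 1 alone gave 22, 201, 13 and 3 for dose trend, high, low and high minus low, and period 2 alone 148, 264 and 39 for the former 3. Without the 3 arrays, low dose had 10, the late change at high dose 335 and at low dose 9.

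Leaving out each course in turn gave 0 to 330 genes for the dose trend, 74 to 901 for high dose, 0 to 47 for low dose and 0 to 178 for high minus low. It gave 6 to 55 and 34 to 256 for the early and late changes at high dose, 0 to 2 and 0 to 1 at low dose, 0 to 10 for the difference in early change, and 0 to 7 lists. The midpoint of the mating response list stayed within its interval, at 1.34 nM by a Hill fit, 1.51 nM at 60 min and 2.05 nM with all members.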

Other observations

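The genes and lists here were chosen after their values were seen, and no test beyond the dose trend and time contrasts was run on them.

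Of the ORFs annotated to the Ty3 retrotransposon, 3 are given here, and how many others the array holds was not counted. YIL082W rose by 0.99 log2 units per 10-fold dose (SE 0.09, adjusted p = 0.00201, limma), with course means of 1.21, 0.28, 1.36, 2.17, 3.82 and 3.97 from the lowest to the highest dose. YIL080W rose by 0.71 (SE 0.13, adjusted p = 0.026) and YIL082W-A by 0.66 (SE 0.15, adjusted p = 0.0439). The element has more than 1 copy, and the spots do not tell copies apart.

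In the 0.6 nM course 8 of 19 lists lay nearer the untreated level at 90 min than at 30 min and 11 lay farther from it, on single arrays. Its G1/S mean was -0.43 at 30 min and 0.10 at 90 min, and its histone mean was -0.80 at 30 min and -0.37 at 90 min, whereas its G2/M mean was 0.02 and -0.32, its M/G1 mean 0.06 and -0.37 and its environmental stress mean 0.04 and 0.30. At 600 nM the histone mean was -1.34 at 30 min and -1.82 at 90 min. The amino acid biosynthesis mean at 600 nM was 0.33 at 90 min and 0.41 at 120 min, against -0.06 at 30 min. GRX3 and MSH6, which lie next to each other, rose by 1.83 and 1.39 from 30 to 90 min of a high dose.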
